A study of Mus musculus with 2 samples.

How the data were processed

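RNA was measured in 2 libraries of in vitro-generated mouse Th17 cells, 1 labelled CREB knockout and 1 wildtype, both of C57BL/6 background. Per the labels' protocols, messenger RNA was enriched from total RNA with a magnetic bead kit and the libraries were prepared and amplified with an RNA-seq kit. The deposited files hold 1 whole-number count of uniquely assigned reads per gene symbol and library, per the file headers, with no normalization by the authors. The submitters' processing notes name bcl2fastq, HTSeq and the genome build mm10 (GRCm38). The aligner, the gene annotation, the strand setting and the treatment of reads that overlap several features are not given in the sources used here. The total in each file header equals the sum of the counts, 23938112 for the library labelled knockout and 26525471 for the wildtype library. The lowest listed count was 1, so genes listed in 1 library only (940 and 721, with at most 18 reads) were taken as 0 in the other. No row for unassigned reads was listed.

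Library sizes were scaled with trimmed mean of M-values factors from edgeR 4.0.16 in R 4.3.3, and ratios were formed after adding a prior count of 0.5 scaled to library size. With 1 library per group, the edgeR quasi-likelihood test could not be fitted and no p-value was computed. Each gene's ratio was given an exact conditional binomial (Clopper-Pearson) 95% interval for counting error. Genes entered if their mean was 1 CPM or more (10462 genes), and Creb1 is reported below that level. A gene was counted as 2-fold apart if its ratio reached 2-fold with 10 CPM in the higher library. Members of gene lists were counted as higher or lower at 1.5-fold or more with an interval excluding 1. For each of 36 gene lists, the median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A list stood apart below the 2.5th or above the 97.5th percentile, and lists with fewer than 5 measured members got no percentile. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

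The lists, the rules and most alternatives were chosen before the data were examined. The genes named are Creb1, up to 12 genes per direction past the 2-fold rule whose interval lay beyond 1.5-fold, up to 4 members of each list with the largest ratios, and a fixed set that includes Il17a, Il17f, Il21, Il22, Foxp3, Il2, Ifng, Il10, Csf2, Ctla4, Crem and Atf1. Results for some genes that the rule takes are not reported here. Gene models without a proper name, small RNAs of host genes and pseudogenes were skipped. Positions are 1-based from GENCODE M21 on GRCm38, and were found for 136 of 137 named genes. Curated transcripts per gene were counted in RefSeq, and for the restriction to genes with 1 of them older symbols were matched as well (15502 of 15574 genes, against 14582 by current symbol).

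The steps were tested on simulated counts for the same 15574 genes. With counting noise alone, 0 genes passed the 2-fold rule and 3 of 40 random lists fell outside the percentile limits. The observed log2 ratios spread more widely than counting noise (SD 0.121 against 0.03 at 100 CPM or more). The simulation therefore gives no rate of false calls for these libraries. Changed genes and random lists were drawn from genes of 10 CPM or more. The rule recovered 67 of 67 genes simulated at 2.5-fold, 67 of 67 at 4-fold and 0 of 66 at 1.5-fold, which its 2-fold limit largely sets. Intervals held the simulated ratio for 94.8% of unchanged genes with a mean of 10 CPM or more.

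Alternatives were scaling by total counts, by DESeq2 1.42.0 size factors and by upper quartiles, no filter or a mean of 10 CPM, a prior count of 5, thinning of the deeper library, an interval bound beyond 2-fold, 1 CPM in the higher library and unmatched random lists. Another 3 were added after the data were seen: a 1.5-fold rule, genes with 1 curated transcript, and lists without Il17a and Il17f. Counts of genes with near-identical copies, such as ribosomal protein, histone and Hspa1a genes, are uncertain because shared reads may have been dropped, and antisense or overlapping genes may share reads if strand was ignored. Both libraries were used in every comparison and no column was left out. Transcript isoforms and the deleted region of Creb1 were not analysed here.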

Results

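Messenger RNA was sequenced from mouse T helper 17 (Th17) cells, the CD4 T cell subset that makes the cytokines IL-17A and IL-17F. Naive T cells of C57BL/6 background, either labelled as lacking CREB or wildtype, were cultured for 6 days with IL-6, TGF-beta, IL-1 beta and IL-23. They were then restimulated through CD3 for 4 h. CREB, encoded by Creb1, is a transcription factor activated by cyclic AMP signalling, and the comparison asks which genes depend on it in Th17 cells. There was 1 library per genotype, with 23938112 counted reads in the library labelled knockout and 26525471 in the wildtype library. Reads were assigned to 14853 and 14634 genes, respectively, of which 13913 were shared. With no replicates, no p-value can be given, and every difference below lies between 2 libraries, not between genotypes. Ratios carry 95% intervals (exact conditional binomial) that cover counting error only, because 1 library per group gives no replicate error. Reads amplified by PCR without molecular identifiers are not independent molecules, so the intervals may be too narrow even for counting error.

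The count of the targeted gene was low in both libraries and not lower in the library labelled knockout. Creb1 (chromosome 1, 64532645 to 64604548, GRCm38) had 25 reads in the library labelled knockout and 13 in the wildtype library, which is 2.08-fold higher in the former (1.04 to 4.51). Its mean level of 0.766 CPM (counts scaled to library size) is among the low ones, and it is annotated with 3 curated RefSeq transcripts. Protein-coding genes with 3 or more had a median of 4.12 CPM, those with 2 or more 5.03 and those with 1 16.1. The share of genes under 1 CPM, where Creb1 lies, was similar by this count, at 32.3%, 30.6% and 29.9%, respectively. It differed when only transcripts of older accession number were counted, at 43.1%, 39.5% and 27.3%. That count was chosen after the result was seen, and Creb1 has 3 such transcripts as well. The position of the deletion is not given in the sources used here, so these reads cannot be placed inside or outside it. The label "knockout" is therefore not borne out by the targeted gene, and each direction below refers to the library labelled knockout.

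The genes for both signature cytokines were lower in the library labelled knockout. Il17f (chromosome 1, 20777146 to 20790617) had 13041 reads against 39898 and was 2.78-fold lower (2.72 to 2.83), the lowest ratio among the 7324 genes that reached 10 CPM in the higher library. Il17a, its neighbour (chromosome 1, 20730905 to 20734496), had 6981 against 13093 reads and was 1.70-fold lower (1.65 to 1.75). Il17a ranked 9 from the lowest among the same 7324 genes. Among the 2162 genes with a mean of 100 CPM or more, Il17f and Il17a had the lowest and second-lowest ratios. Il23r, which encodes a subunit of the IL-23 receptor, was 1.43-fold lower (1.28 to 1.60), while the cytokine gene Il9 was 1.84-fold higher (1.70 to 2.00).

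**Figure D1:**
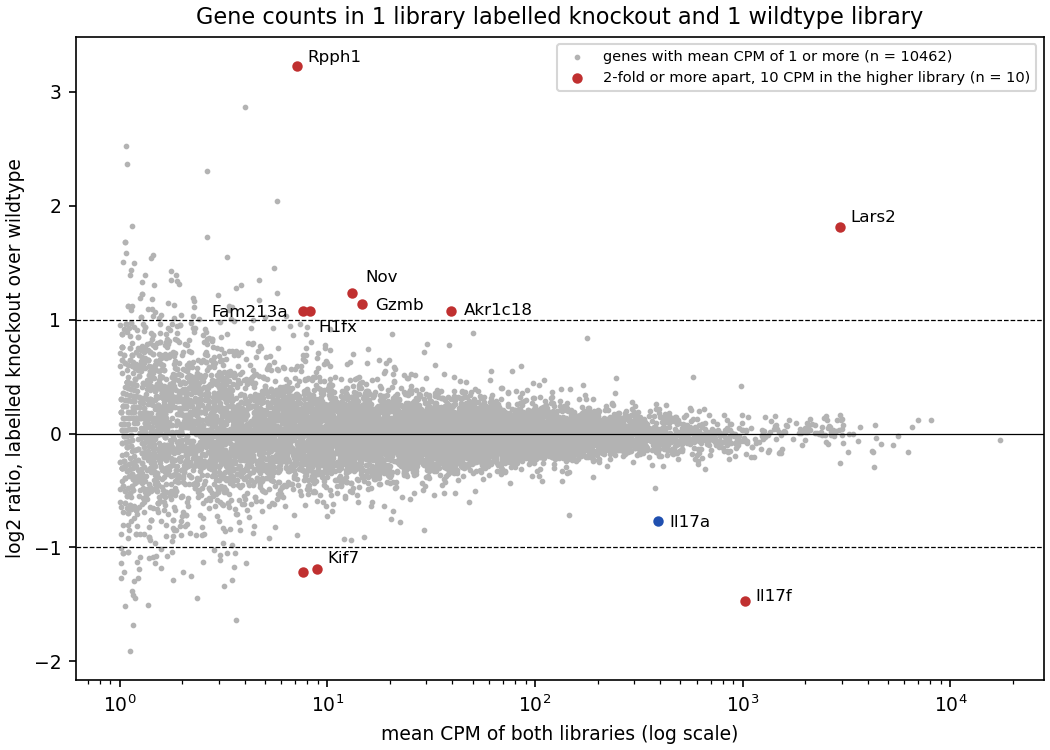
Each point is 1 gene, with the mean CPM of both libraries on a log axis and the log2 ratio of the library labelled knockout over the wildtype library on the vertical axis. The 10 genes that were 2-fold or more apart with 10 CPM in the higher library are red, and all but 1 are named; Il17f and Lars2 lie far from the other abundant genes, and Il17a (blue, log2 ratio -0.77) lies below them.

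Outside these genes the 2 libraries were close. Of the 7324 genes with 10 CPM in the higher library, 91.4% were within 1.2-fold, and log2 CPM correlated across those genes with a Pearson r of 0.994 (genes are not independent replicates). Across the 2162 genes with a mean of 100 CPM or more, log2 ratios had an SD of 0.121, against a median counting SD of 0.03. The libraries thus differed by more than counting error. An interval that excludes 1 therefore does not by itself set a gene apart from this spread. In all, 7 genes were 2-fold or more higher and 3 were 2-fold or more lower in the library labelled knockout. The higher genes were Rpph1, the RNA component of RNase P, at 9.37-fold (6.71 to 13.8); Lars2, the mitochondrial leucyl-tRNA synthetase, at 3.53-fold (3.48 to 3.57); Nov, a secreted matricellular protein, at 2.35-fold (2.00 to 2.79); and Gzmb, the cytotoxic protease granzyme B, at 2.21-fold (1.89 to 2.59). Fam213a was higher at 2.12-fold (1.71 to 2.64), the aldo-keto reductase gene Akr1c18 at 2.11-fold (1.92 to 2.32) and the linker histone gene H1fx at 2.11-fold (1.72 to 2.61). The lower genes included, besides Il17f, Kif7, a kinesin of the Hedgehog pathway, at 2.28-fold lower (1.86 to 2.83). Lars2 reached 4598 CPM in the library labelled knockout, against 1304 in the wildtype library, and whether all of these reads come from its messenger RNA or in part from similar sequence elsewhere, such as ribosomal RNA, was not settled. The whole interval was beyond 2-fold for 2 of the 7 higher genes and 1 of the 3 lower genes.

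Th17 cytokine and receptor genes had a low median in the library labelled knockout, with members going both ways. Of 14 measured members, 2 were lower by 1.5-fold or more with an interval excluding 1 (Il17a and Il17f), 1 was higher (Il9), and 11 were neither, while 4 members had an interval above 1 and 4 below. Their median log2 ratio was -0.21, below all of 10000 random lists matched on expression (percentile 0). The granulocyte-macrophage colony-stimulating factor gene Csf2 was 1.39-fold higher (1.21 to 1.60). Il21 was 1.10-fold lower (1.08 to 1.13), and Il22 had only 40 against 55 reads, a ratio of 0.803 (0.520 to 1.23) that leaves either direction open. Over the 10 members with a mean of 10 CPM or more the median was 0.06 (percentile 93.1), and without Il17a and Il17f the percentile was 9.78.

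None of 15 measured transcription factor genes of the Th17 program was 1.5-fold apart with an interval excluding 1, and the list median of -0.03 lay at percentile 33.0. Rora was 1.30-fold lower in the library labelled knockout (1.10 to 1.54), the aryl hydrocarbon receptor gene Ahr 1.24-fold lower (1.11 to 1.40) and Batf 1.14-fold lower (1.08 to 1.20). Prdm1 had 46 against 34 reads and a ratio of 1.48 (0.937 to 2.40).

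The published split of Th17 genes into pathogenic and non-pathogenic ones gave no list that stood apart. Of 17 pathogenic Th17 genes, Gzmb was higher and the chemokine gene Cxcl3 was lower, at 2.06-fold (1.31 to 3.36) on 28 against 64 reads, and 15 were neither (median -0.08, percentile 6.84). Of 7 non-pathogenic genes, Il9 was higher and 6 were neither (median -0.03, percentile 37.3). Il10, from this list, had 125 against 170 reads and was 1.23-fold lower with an interval that includes 1 (0.974 to 1.57).

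Regulatory T cell (Treg) genes had the highest percentile of all lists, with small ratios. The 21 measured members had a median log2 ratio of 0.14, above all of 10000 random lists (percentile 100), and 11 had an interval above 1 against 3 below. None was 1.5-fold higher, 20 were neither, and Entpd1, which encodes the ectonucleotidase CD39, was 1.53-fold lower (1.06 to 2.24). Tigit, an inhibitory receptor gene, was 1.29-fold higher (1.03 to 1.62), Socs2 was 1.29-fold higher (1.18 to 1.40) and Ctla4 was 1.04-fold higher with an interval that includes 1 (0.989 to 1.10). Foxp3, which encodes the lineage factor of Treg cells, had 3 against 5 reads, a ratio of 0.693 (0.103 to 3.40), too few for a direction. The list no longer stood apart without the filter on low counts (percentile 92.6) or over its members with 1 curated RefSeq transcript (percentile 58.5).

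**Figure D2:**
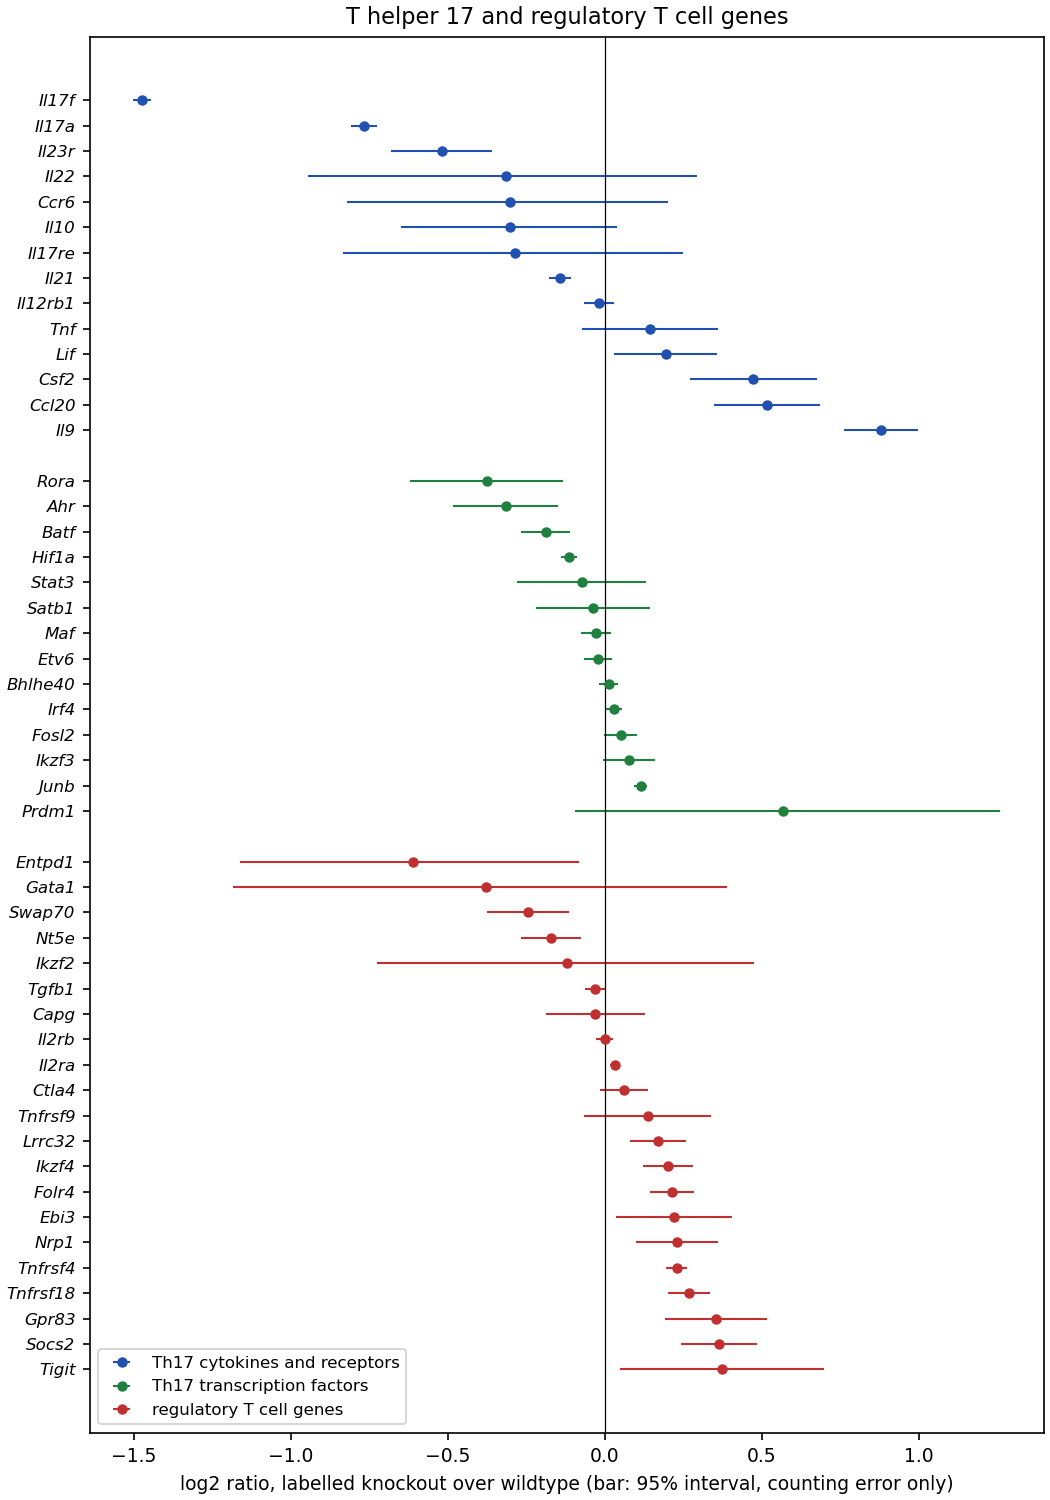
Points are log2 ratios of the library labelled knockout over the wildtype library for the measured members of the Th17 cytokine and receptor (14), Th17 transcription factor (15, of which 1 is not drawn) and regulatory T cell (21) lists, and bars are 95% intervals for counting error only. Il17f and Il17a have the lowest ratios, Il9 the highest, and the Treg genes lie mostly a little above 0.

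Genes of the CREB family went both ways. Of 11 measured members of the CREB family and its coactivators, Atf7 was 1.59-fold higher (1.31 to 1.93) and 10 were neither (median 0.04, percentile 86.0). Crebbp, the histone acetyltransferase that binds CREB, was 1.34-fold higher in the library labelled knockout (1.27 to 1.42), and Atf4 was 1.18-fold lower (1.07 to 1.29). The close relatives of Creb1 were not far apart: Crem had 147 against 198 reads and a ratio of 0.819 (0.657 to 1.02), and Atf1 was 1.08-fold lower (1.02 to 1.14). Crem is annotated with 19 curated RefSeq transcripts, and if reads shared by several transcripts were not counted, its ratio rests on part of its reads. The list stood above random lists without the filter on low counts, which adds Creb1, Creb5 and Atf2 (percentile 99.1), and over its members with 1 curated transcript, which leaves Creb1 out (98.5).

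Among 21 measured cAMP and CREB target genes, Il2 was higher, Areg was lower and 19 were neither (median 0.04, mean just below 0, percentile 91.9). Il2, the T cell growth factor gene, was 1.53-fold higher in the library labelled knockout (1.35 to 1.75), and Areg, which encodes the growth factor amphiregulin, was 1.51-fold lower (1.30 to 1.77). Fos was 1.40-fold lower (1.23 to 1.58) and Sik1 1.26-fold higher (1.17 to 1.37). None of the 21 immediate early genes, which T cell stimulation induces within minutes to hours, was 1.5-fold apart (median -0.01, percentile 57.0). Klf4 was 1.29-fold lower (1.18 to 1.42) and Atf3 1.24-fold higher (1.14 to 1.34).

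Lists of other helper subsets were at or below the middle of the random lists. Of 11 measured Th1 genes, Gzmb was higher, the chemokine receptor gene Cxcr6 was 1.55-fold lower (1.23 to 1.97) and 9 were neither (median -0.14, percentile 2.20). Ifng, the signature Th1 cytokine gene, had 11 against 6 reads and a ratio of 1.94 (0.685 to 6.65). Of 10 follicular helper genes, none was 1.5-fold apart (median -0.11, percentile 1.98); the costimulatory receptor gene Icos was 1.16-fold lower (1.14 to 1.19) and Cd200 1.18-fold higher (1.14 to 1.23). The Th1 list left the outer range with thinned counts (percentile 3.83), a larger prior count (2.69), no filter on low counts (2.76) and 1 curated transcript per gene (15.8), and the follicular list with members of 10 CPM or more (51.6) and unmatched random lists (3.68). None of 7 Th2 genes was 1.5-fold apart (median -0.04, percentile 31.9), with Ecm1 1.32-fold lower (1.20 to 1.45) and Ccr4 1.11-fold higher (1.08 to 1.14).

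Most listed cell cycle and protein-folding genes had ratios a little below 1 in the library labelled knockout. None of 28 cell cycle genes was 1.5-fold apart, but 25 had a ratio below 1 and 3 above, with 16 intervals below 1 and 1 above (median -0.09, percentile 0.17). Over the 16 members with 1 curated transcript this list no longer stood apart (percentile 2.83), and 26 replication-dependent histone genes, which are also tied to proliferation, went the other way (median 0.31, percentile 99.96). Histone transcripts of this kind lack poly(A) tails, so in libraries enriched for messenger RNA their counts may not track proliferation. Mcm3, a subunit of the replicative helicase, was 1.20-fold lower (1.17 to 1.23). Of 16 protein folding and endoplasmic reticulum (ER) stress genes, 14 had a ratio below 1, 13 an interval below 1 and none was 1.5-fold apart (median -0.15, percentile 0.01). Dnajc3 was 1.25-fold lower (1.19 to 1.32), the ER chaperone gene Hspa5 1.24-fold lower (1.03 to 1.49) and the disulfide isomerase gene Pdia6 1.21-fold lower (1.18 to 1.25). None of 11 cytosolic and mitochondrial heat shock genes was 1.5-fold apart (median -0.07, percentile 9.78). Hsp90aa1 was 1.15-fold lower (1.13 to 1.17) and Dnaja1 1.34-fold lower (1.13 to 1.59), and over members with 10 CPM or more this list stood below random lists (percentile 2.11).

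Feedback and signalling genes of the JAK-STAT pathway had a high median with members going both ways (0.13, percentile 99.98). None of 17 members was 1.5-fold apart, 12 had a ratio above 1 and 5 below, and 6 had an interval above 1 against 2 below. The kinase gene Pim1 was 1.16-fold higher in the library labelled knockout (1.13 to 1.20) and the receptor gene Il6st 1.15-fold higher (1.04 to 1.28). The list did not stand apart over members of 10 CPM or more (percentile 94.4) or over those with 1 curated transcript (77.2). Of 41 ribosomal protein genes, 23 had an interval above 1 and 5 below, 40 were neither and Rpl22 was lower, at 2.12-fold (1.23 to 3.89) on 19 against 45 reads. Rpl22 has 5 curated transcripts, so its ratio may also rest on part of its reads. The median of this list was 0.04 (percentile 99.87; 90.4 among unmatched random lists), and Rps20 and Rplp1 were each 1.11-fold higher (1.10 to 1.13 and 1.10 to 1.12). All 5 measured long or nuclear-retained RNAs had intervals above 1, with none 1.5-fold apart (median 0.23, percentile 99.98). Malat1 was 1.41-fold higher (1.38 to 1.44) and Kcnq1ot1 1.23-fold higher (1.15 to 1.32).

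T cell activation genes did not stand apart (median 0.07, percentile 97.3), with Il2 higher, the chemokine gene Xcl1 2.01-fold lower (1.25 to 3.40) and 18 of 20 neither. This list passed the upper limit with thinned counts (percentile 98.8) and over members of 10 CPM or more (97.8). Of 10 inhibitory receptor genes, Entpd1 was lower and 9 were neither (median 0.06, mean -0.03, percentile 79.9), and Pdcd1lg2, which encodes a ligand of PD-1, was 1.45-fold higher in the library labelled knockout (1.27 to 1.65). Of 17 chemokine and receptor genes, Cxcl3, Xcl1 and Cxcr6 were lower and 14 were neither. The chemokine median was -0.07 (percentile 11) but turned to 0.10 (percentile 98.5) over the 11 members of 10 CPM or more. Of 14 naive and memory T cell genes, Foxp1 was 1.59-fold higher (1.21 to 2.10) and 13 were neither (median -0.06, mean 0.02, percentile 11.9). None of 13 T cell receptor and lineage genes was 1.5-fold apart (median 0.01, mean -0.04, percentile 76.1), with Cd4 1.07-fold lower (1.05 to 1.09). Of 14 TGF-beta pathway genes none was 1.5-fold apart (median 0.05, percentile 88.9), and Tgfb3 was 1.33-fold lower (1.09 to 1.63).

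The glycolysis, oxidative phosphorylation, cholesterol synthesis, integrated stress response, apoptosis, interferon and housekeeping lists lay inside the range of random lists under the main settings. None of 18 glycolysis genes was 1.5-fold apart (median 0.01, percentile 77.25), with the glucose transporter gene Slc2a1 1.19-fold higher (1.15 to 1.22). Of 30 oxidative phosphorylation genes, Ndufs1 was higher, at 1.83-fold (1.02 to 3.47) on 32 against 19 reads, and 29 were neither (median -0.01, mean 0.03, percentile 61.1). None of 20 cholesterol synthesis genes was 1.5-fold apart (median 0.04, percentile 94.7), with Cyp51 1.17-fold lower (1.12 to 1.21) and Lss 1.13-fold higher (1.06 to 1.21), and over members of 10 CPM or more this list just passed the limit (97.515). Of 19 integrated stress response genes, Nupr1 was 1.54-fold higher (1.32 to 1.81) and 18 were neither (median 0.03, percentile 80.7), with the serine synthesis gene Psat1 1.43-fold lower (1.10 to 1.86). None of 23 apoptosis and survival genes was 1.5-fold apart (median 0.01, percentile 65.5), with the BH3-only gene Bbc3 1.21-fold higher (1.11 to 1.31). Of 24 interferon response genes, Ifi44 was lower, at 2.42-fold (1.38 to 4.57) on 17 against 46 reads, and 23 were neither (median 0.02, mean -0.08, percentile 77.5). Isg15 was 1.25-fold lower (1.11 to 1.42). None of 16 housekeeping genes was 1.5-fold apart (median -0.05, percentile 10.6), with Actb 1.09-fold higher (1.08 to 1.09) and Gapdh 1.07-fold lower (1.06 to 1.08).

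**Figure D3:**
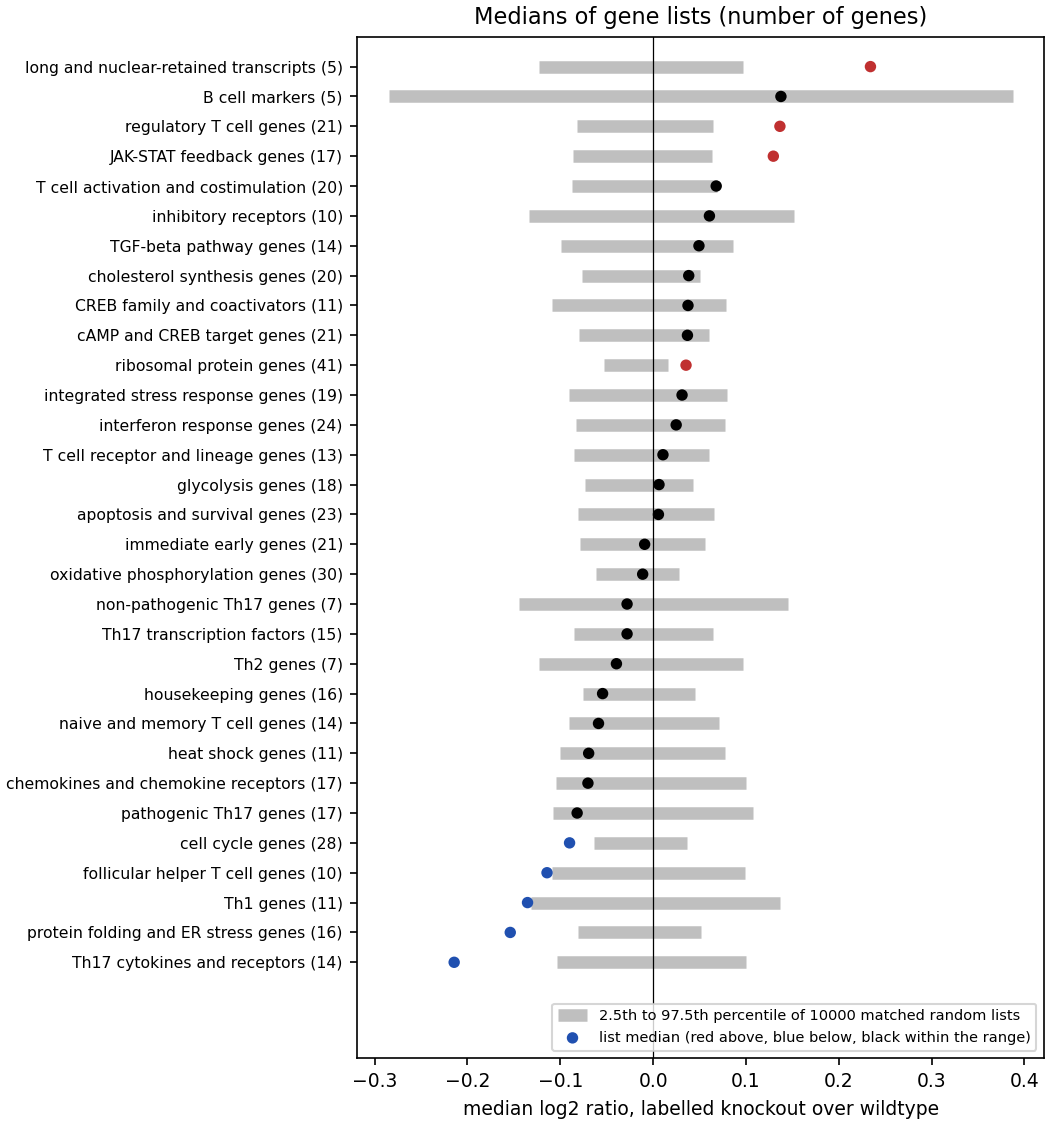
Points are the median log2 ratios (library labelled knockout over wildtype library) of the 31 gene lists with at least 5 measured genes, and grey bars span the central 95% of 10000 random lists matched on size and expression. The Th17 cytokine list lies furthest below its range, at -0.21, and the long or nuclear-retained RNAs furthest above, at 0.23.

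Of 31 lists with a percentile, 4 were above and 5 below the range of their random lists. Lists share members and hold genes regulated together, so these counts have no simple chance value. Few of the listed markers of other cell types reached a mean of 1 CPM, but some that did had many reads. Reads of some genes may have been dropped in counting, so low counts do not show that such cells were absent. Of the B cell markers, 5 were measured and none was 1.5-fold apart (median 0.14, percentile 76.6), with Cd79a at 26 reads in each library and Cd74 1.18-fold higher in the library labelled knockout (1.05 to 1.34). The most abundant, H2-Ab1, had 1575 against 1758 reads and a ratio of 0.987 (0.922 to 1.06). The myeloid list had 3 measured genes (median -0.17), and all were neither higher nor lower. Among them, Cst3 had 2431 against 2817 reads and a ratio of 0.951 (0.901 to 1.0045). The NK, CD8 and gamma-delta T cell list had 4 measured genes (median -0.14), all neither, with Klrd1 1.32-fold lower (1.13 to 1.54) and Cd8b1 at 234 against 237 reads. The erythroid and platelet list had 1 measured gene, Itga2b, with a ratio of 1.21 (0.864 to 1.71). Of the sex-linked genes, Xist had a ratio of 0.994 (0.968 to 1.02) at 436 and 439 CPM, and 0 of the 13 mitochondrially encoded genes were listed.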

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

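The 1.5-fold rule, the restriction to genes with 1 curated transcript and the lists without Il17a and Il17f were chosen after the data were seen. Scaling by total counts, DESeq2 size factors or upper quartiles shifted log2 ratios by at most 0.0086 and left the counts within 1.5 times and every list on its side of the limits. Of the list values, 253 stayed on their side of the limits, but for 13 of these, all from lists that did not stand apart, the median changed sign. All 680 values of named genes kept their direction. The main counts of 7 higher and 3 lower genes became 4 and 1 with a mean of 10 CPM, 2 and 1 with the interval bound beyond 2-fold, 70 and 46 with 1 CPM in the higher library, and 36 and 23 under the 1.5-fold rule. The direction of these moves follows from the settings' own construction, but their size does not. Most genes counted as 2-fold apart with 1 CPM in the higher library did not reach 10 CPM there. Of the 7 higher genes, 4 have 1 curated transcript, and Lars2, Fam213a and Akr1c18 have several. Creb1 has no value with a mean of 10 CPM. No replicate could be left out.

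Values for lists are percentiles. Without the filter on low counts, CREB family genes moved to 99.14, Treg genes to 92.64 and Th1 genes to 2.76. With a mean of 10 CPM, Th17 cytokines and receptors turned to 93.06, follicular helper genes to 51.65 and chemokines to 98.54, JAK-STAT genes went to 94.425, and T cell activation (97.845), cholesterol synthesis (97.515) and heat shock genes (2.11) passed a limit. A prior count of 5 put Th1 genes at 2.695, and thinning put them at 3.835 and T cell activation genes at 98.79. Unmatched random lists gave 3.68 for follicular helper and 90.385 for ribosomal protein genes. Over genes with 1 curated transcript, CREB family genes stood at 98.545, Treg genes at 58.54, Th1 genes at 15.8, JAK-STAT genes at 77.175 and cell cycle genes at 2.83. Without Il17a and Il17f, the Th17 cytokine list stood at 9.78. The cause of the list moves was not tested. Few reads leave wide intervals for Creb1, Foxp3, Ifng and Il22.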

Other observations

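The test of the Il17a and Il17f pattern, the exchange of labels and the count of transcripts by older accession number were chosen only after the result was seen; the other tests were set before. The following genes lie outside the naming rule, were chosen after their values were seen and stand for no group. Adora2a, an adenosine receptor that raises cyclic AMP, was 1.64-fold higher in the library labelled knockout (1.48 to 1.83). Il1r2, a decoy receptor for IL-1, was 1.90-fold lower (1.60 to 2.26), Lpar6, a receptor for lysophosphatidic acid, 1.88-fold lower (1.62 to 2.20), and Gpr183, an oxysterol receptor that guides lymphocyte migration, 1.52-fold lower (1.40 to 1.65). Cd24a, which encodes a small surface glycoprotein, had 2642 against 4778 reads and was 1.64-fold lower (1.56 to 1.72). Basp1 was 1.78-fold higher (1.71 to 1.86) at a mean of 178 CPM.

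Also chosen after their values were seen, Ptch1, the Hedgehog receptor gene, was 1.57-fold higher in the library labelled knockout (1.38 to 1.78), whereas Kif7 of the same pathway was 2.28-fold lower (1.86 to 2.83). Notch3 was 1.75-fold higher (1.43 to 2.15).

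Creb1 had 25 and 13 reads, and other multi-transcript genes expressed in T cells, chosen after their values were seen, were also sparse: Ptprc had 75 and 81 reads, Ldha 37 and 39, Foxp3 3 and 5, and Myc 0 in both, while others were abundant, with 11477 and 13964 reads for Il21 (2 curated coding transcripts, each of older accession number), 3586 and 4462 for Cd247 (4, all older), 10854 and 13426 for Hspd1 (2, of which 1 is older) and 110368 and 34502 for Lars2 (3, of which 1 is older). A candidate explanation for the low counts of part of these genes is that reads shared by several transcripts were not counted, though Il21 and Cd247 go against it. Protein-coding genes with 2 or more curated RefSeq transcripts had a median of 5.03 CPM against 16.1 for those with 1, a ratio of 0.312, which lies between the bounds set in advance, and with transcripts of older accession number only the ratio was 0.0960 (1.78 against 18.5 CPM), as this explanation needs. An exchange of the library labels cannot be told apart from a detection failure. Nor can it be told apart from reads outside the deleted region, whose position is not given. The lower bound of the Creb1 ratio is 1.04, but there is no second marker of the deletion. Whether Creb1 was deleted stays open.

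Rpph1 (9.37-fold) and Lars2 (3.53-fold) were the genes with the highest ratios past the 2-fold rule, and Rpph1 RNA has no poly(A) tail. One hypothesis is more carry-over of RNA without poly(A) tails into the library labelled knockout. Only 2 other small RNAs of this kind were measured, with a median log2 ratio of 1.44, above the bound of 0.5 set in advance, from Rmrp at 7.32-fold higher (4.88 to 11.8) and Snora81 at 1.002-fold (0.590 to 1.69), which are too few to decide. The 26 measured replication-dependent histone genes, whose transcripts also lack tails, had a median of 0.31, between the bounds set in advance, at percentile 99.96 of matched random lists with 7 intervals above 1 and 1 below, and the list of 5 long or nuclear-retained RNAs, of which Gas5 and Snhg12 are spliced hosts of small RNAs, was higher too (median 0.23, percentile 99.98), so carry-over cannot be told apart from other causes. A difference due to genotype stays open and untested, since the genotype and the library are the same split.

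Il17f (log2 ratio -1.47) and Il17a (-0.77) were lower in the library labelled knockout, though the Creb1 count does not bear out that label. A smaller share of cells making both transcripts at a fixed level would lower both alike, whereas the upper bound for Il17f of -1.44 lies below the lower bound for Il17a of -0.81. These bounds cover counting error only, with 1 library per group, so this explanation cannot be told apart from the others. Besides this explanation, a different makeup of the cultures that lowers both transcripts unequally stays open. So do lower transcription or stability of both genes per cell, as a hypothesis about genotype, and variation between cultures, which 1 library per group may hide.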
